A study of Mus musculus with 28 samples.

How the data were processed

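The labels listed 28 libraries in 6 groups, 14 per tissue, and 8 comparison tables were used, 4 per tissue, made by the authors with DESeq2 on genome build mm10 per the submitters' processing notes. The aligner, the read counter and the annotation were not given in the sources used here, and per-library counts were not used here. The log2 fold changes and their standard errors were computed by the authors with DESeq2 and taken as deposited. The score column, the Wald statistic of a pair or the statistic of the test over the 3 groups of a tissue, was computed by the authors and taken as deposited. The p-values and adjusted p-values were computed by the authors and taken as deposited, with the adjusted p missing where their filter had removed the gene. The mean normalised count (baseMean) was computed by the authors over all libraries of a tissue, as deposited.

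For each pair of groups there was a table of the pairwise Wald test and a table of the 3-group test. The fold changes of both were equal in size with opposite sign, except for TURI against GF in the small intestine, where the Wald table held shrunken values with a largest standard error of 0.219 against 1.59 unshrunken. Fold changes of single genes and list medians of that comparison are therefore given unshrunken from the 3-group table, and calls use the adjusted p of the Wald table. The list tests, the tests of differences and the correlation of TURI with SPF used the shrunken values of the Wald table, with unshrunken values as an alternative. The sign was settled from genes known to be induced by a microbiota, of which 7 of 7 were higher in SPF and called in the small intestine. In the colon 6 of 7 were higher but 0 of those were called, and 1 was lower and called, so the colon sign rests mainly on the shared layout of the tables. With TURI, none of these genes was called in either tissue, so they did not settle its sign. That sign was carried over from SPF by the positive covariance of their fold changes, which shared GF libraries force. It was 0.0296 in the small intestine, unshrunken, and 0.0523 in the colon.

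A gene was called at an adjusted p under 0.05. Genes were named by a rule fixed before the data were examined. It took the 8 largest rises and the 8 largest falls among called genes with a baseMean of at least 20. Predicted genes among these rises and falls were left unnamed. The rule also took the 5 smallest p at any baseMean. Up to 4 members with the smallest p were added from each list that was called or had at least 2 called members, with a fixed set given always. Genes that differed or were shared between comparisons were named as well. Gene coordinates are those of GENCODE M21 on GRCm38.

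Gene lists numbered 39 and were fixed before the data were examined. They were tested with cameraPR of limma 3.58.1 in R 4.3.3 on the signed statistic, with a preset inter-gene correlation of 0.01, at least 5 measured members and Benjamini-Hochberg adjustment over the lists of a comparison. Means of 10000 random lists matched in 20 bins of expression served as an alternative. Members were also adjusted over the list alone from the authors' p-values. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

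Differences between comparisons were tested as the difference of the authors' fold changes over the root of the summed squared standard errors, with a normal p and Benjamini-Hochberg adjustment. For tissues this error is too large if both samples came from the same mice, which the labels do not state. For SPF against TURI it ignores the shared GF libraries, which makes it too large in the colon. In the small intestine the shrunken TURI errors work the other way for genes with wide errors, so it is no upper bound there. Shared GF libraries were imitated in 200 simulations of unchanged groups with genes drawn independently, and correlations used genes with a baseMean of at least 20. Intervals of 95% came from 10000 bootstrap draws of genes.

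In a self-test of the tissue difference for TURI with 13870 genes, 73 of 100 genes changed by 1 log2 unit and 100 of 100 changed by 2 were recovered, with 7 false calls. For the tissue difference of SPF with 13870 genes the counts were 71, 98 and 4. For SPF against TURI they were 59, 96 and 7 in the small intestine with 14623 genes and 60, 91 and 6 in the colon with 14776 genes. These simulations used unshrunken errors and drew both fold changes of a gene independently. They therefore checked neither the shrunken TURI values of the small intestine nor the shared GF libraries. For lists in the colon TURI comparison with 14776 genes, 20 of 20 lists of 20 genes shifted by 1 in the statistic were recovered, with 0 false calls among 20 unshifted lists. The statistics were drawn independently, so false calls from inter-gene correlation were not checked.

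The authors' p-values rest on 4 or 5 libraries per group with the sexes mixed. Reads of near-identical copies, among them the Defa, Iglc, Hba-a1 and Hba-a2, Hspa1a and Hspa1b, Saa1 and Saa2 and Ces2 genes, cannot be assigned with certainty.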

Results

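The study held 28 libraries of 3' end RNA-seq from C57BL/6 mice, 14 from the terminal ileum, called small intestine in the labels, and 14 from the distal colon. QuantSeq FWD, the kit used, reads a tag near the 3' end of each transcript, so the values count transcripts and carry little information on splicing. In each tissue, 5 libraries came from germ-free mice (GF), which carry no microorganisms. Another 4 came from formerly germ-free mice kept for 2 weeks with a single bacterium, Turicibacter sanguinis MOL361 (TURI), a spore-forming gut commensal. The remaining 5 came from specific pathogen free mice (SPF), which carry a complex microbiota. The GF and SPF groups held 3 males and 2 females each, and the TURI groups 2 males and 2 females. The mice were 7 weeks old by the design text, which named 5 animals per group, whereas the labels listed 4 TURI libraries per tissue.

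The values used were the authors' own comparison tables, with 14623 genes in the small intestine and 14776 in the colon, of which 13870 were in both. Depth per library was unknown here. The transcript Gm42418, which overlaps ribosomal RNA sequence, took 10.7% of the summed mean normalised counts in the small intestine and 10.3% in the colon. As a check on the labels, the sex-linked genes had wide errors and no call in any comparison. In the authors' deposited table of the colon TURI comparison, Xist had a log2 fold change of 0.41 ± 1.69 (SE) and Ddx3y of -0.13 ± 1.61, as groups of mixed sex give. In the small intestine the corresponding values of the authors' deposited table, unshrunken, were 0.29 ± 1.59 for Xist and -0.37 ± 1.40 for Ddx3y.

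**Figure D1:**
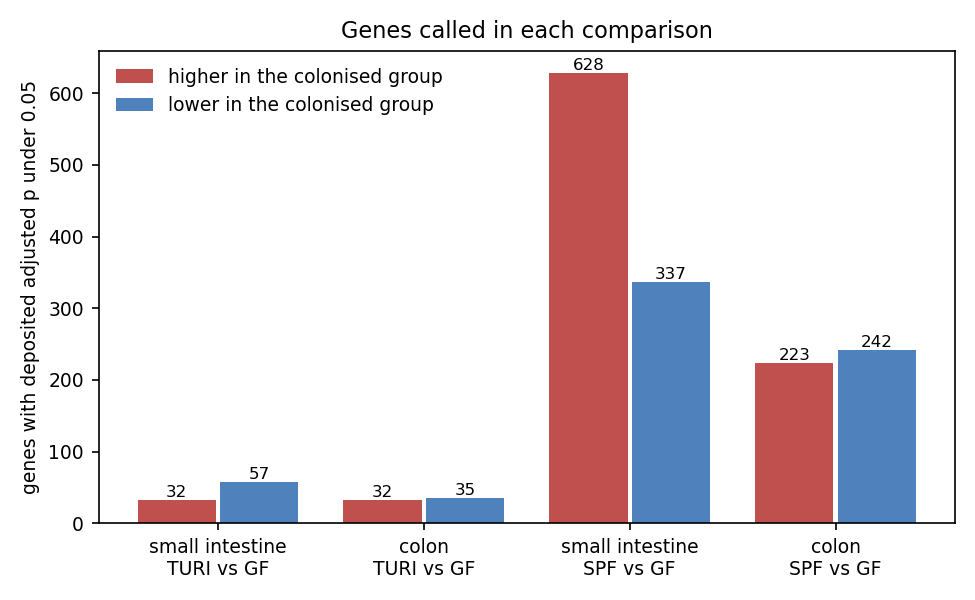
Number of genes with an adjusted p under 0.05 in the authors' deposited table of each comparison with GF, on the vertical axis, as red bars for genes higher and blue bars for genes lower in the colonised group. TURI had 32 higher and 57 lower genes in the small intestine and 32 and 35 in the colon, while SPF had 628 and 337 in the small intestine and 223 and 242 in the colon.

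The comparison of TURI with GF in the small intestine asked which host genes respond to this single species. Several genes of cholesterol synthesis, the clock genes Per3 and Tef, the maltase gene Mgam and the glucose transporter gene Slc5a1 fell, and 4 contractile genes of smooth muscle rose. The 4 comparisons with GF were tested for 35 lists in the small intestine and 37 in the colon. Of 12630 genes with an adjusted p in the authors' deposited table, 32 were higher and 57 lower in TURI, and the median change among these 89 was 1.62-fold. Hmgcs1, the cytosolic synthase that feeds 3-hydroxy-3-methylglutaryl-CoA into cholesterol synthesis (ENSMUSG00000093930, chromosome 13, 119690379 to 119708260, protein coding), had a log2 fold change of -0.71 ± 0.11 (SE) in the authors' deposited table, with an adjusted p of 4.03e-07 by the DESeq2 Wald test. The smallest adjusted p of the authors' deposited table, 1.6e-09, belonged to Neat1, the long noncoding RNA that builds paraspeckles (ENSMUSG00000092274, chromosome 19, 5824708 to 5845478, lincRNA), which was 1.69-fold lower. In that comparison the fold changes quoted for single genes are unshrunken and come from the authors' deposited table of the 3-group test, while the adjusted p-values come from the authors' deposited table of the pairwise Wald test.

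Single immediate early genes were among the largest falls, although their list was not called (16 measured, 1 higher and 2 lower, 3 higher and 3 lower when adjusted over the list alone, cameraPR adjusted p = 0.123). The authors' deposited table gave log2 fold changes of -1.22 ± 0.19 for Fos (ENSMUSG00000021250, chromosome 12, 85473890 to 85477273), with an adjusted p of 4.03e-07, and -1.71 ± 0.31 for Atf3, a stress-response transcription factor, with an adjusted p of 0.000237. Cldn4, a tight junction claudin, and Fam84a were 1.85-fold and 1.87-fold lower in the authors' deposited table. The largest rises in the authors' deposited table were those of Depp1, a FOXO target (log2 fold change 2.00 ± 0.35, adjusted p = 8.33e-06; ENSMUSG00000048489, chromosome 6, 116650609 to 116652794), and Fst, the activin antagonist follistatin (1.64 ± 0.34, adjusted p = 0.000468). Nrg1, an epidermal growth factor family ligand, Ahrr, a repressor of the aryl hydrocarbon receptor, and Il1r1, the receptor of interleukin-1, were 2.67-fold, 2.61-fold and 2.52-fold higher in the authors' deposited table. Ddit4, an inhibitor of mTORC1 signalling, was 1.81-fold higher there, with an adjusted p of 4.07e-06.

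By group, the sterol biosynthesis list had 24 measured members, all of them with a fold change below 0. Of these 8 fell and 0 rose by the authors' adjusted p, 17 fell when adjusted over the list alone, and the median log2 fold change was -0.49 (cameraPR adjusted p = 7.49e-27). Besides Hmgcs1, the authors' deposited table gave log2 fold changes of -0.69 ± 0.13 for Msmo1 and -0.63 ± 0.13 for Fdft1. Of 19 measured circadian clock genes, 3 fell (Per3, Tef and Bhlhe40), 0 rose and 16 did not pass, with 11 lower and 2 higher when adjusted over the list alone (cameraPR adjusted p = 1.15e-07). By the authors' deposited table Per3 had a log2 fold change of -0.99 ± 0.18 (ENSMUSG00000028957, chromosome 4, 151003652 to 151044665) and Tef of -0.84 ± 0.19. All 14 measured smooth muscle markers had a fold change above 0: 4 rose, 13 when adjusted over the list alone, and the median log2 fold change was 0.39 (cameraPR adjusted p = 4.15e-16). The 4 were Acta2, Flna, Myl9 and Tagln, with log2 fold changes in the authors' deposited table of 0.42 ± 0.11, 0.46 ± 0.13, 0.42 ± 0.11 and 0.57 ± 0.15.

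Lists of absorptive functions were lower with TURI in the small intestine. Of 8 measured genes of carbohydrate digestion and transport, 2 fell (Mgam, a brush border maltase, and Slc5a1, the sodium-glucose cotransporter), 0 rose and 6 did not pass. When adjusted over the list alone, 5 fell (median log2 fold change -0.52, cameraPR adjusted p = 2.05e-07), and in the authors' deposited table Mgam stood at -0.52 ± 0.12 and Slc5a1 at -0.64 ± 0.17. The amino acid and peptide transport list was lower as a whole (16 measured, median -0.41, cameraPR adjusted p = 1.5e-05), with 8 lower and 1 higher when adjusted over the list alone, although its 1 gene past the authors' threshold, Slc38a2, rose 1.35-fold in the authors' deposited table. Ion and water transport was lower too (17 measured, 1 lower, 2 when adjusted over the list alone, median -0.35, cameraPR adjusted p = 0.000639). Lipid uptake and chylomicron assembly (23 measured, median -0.21, cameraPR adjusted p = 0.00101) held 1 fall, of Npc1l1, the transporter that takes up dietary cholesterol, at -0.70 ± 0.17 in the authors' deposited table, and 2 when adjusted over the list alone. With a preset inter-gene correlation of 0.1 in place of 0.01, the lipid list had an adjusted p of 0.0733. This correlation cannot be estimated without values per library, so it was set to 0.01 and varied to 0.05 and 0.1.

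Region markers of both ends of the small intestine were lower with TURI. The distal list had 12 measured members, 0 past the authors' threshold and 7 lower when adjusted over the list alone (median -0.47, cameraPR adjusted p = 2.14e-09). The proximal list had 12 members, 1 lower and 3 when adjusted over the list alone (median -0.37, cameraPR adjusted p = 0.00458, and adjusted p = 0.0716 at a correlation of 0.1). The 2 lists shared 1 member, Cubn. Goblet cell markers had 13 measured members, 0 past the authors' threshold and 1 lower when adjusted over the list alone (median -0.11, cameraPR adjusted p = 0.0034, and adjusted p = 0.0716 at a correlation of 0.1). Against random lists matched in expression the goblet list had an adjusted p of 0.148 and was not called.

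Other lists were higher with TURI in the small intestine without a single member past the authors' threshold. Macrophage and dendritic cell markers had 13 of 15 members above 0 (median 0.33, 1 higher when adjusted over the list alone, cameraPR adjusted p = 0.000105) and fibroblast markers all 12 (median 0.22, 2 higher when adjusted over the list alone, cameraPR adjusted p = 0.000381). Cell cycle genes had 20 of 24 above 0 (median 0.16, 1 higher when adjusted over the list alone), with a cameraPR adjusted p of 0.00177 that became an adjusted p of 0.0941 at a correlation of 0.1. Paneth cell markers (14 measured, median 0.10, cameraPR adjusted p = 0.0245) and MHC class II genes (9 measured, median 0.20, cameraPR adjusted p = 0.0349) had 0 members higher when adjusted over the list alone, and each had an adjusted p of 0.076 at a correlation of 0.05. Microbe-induced epithelial defence had 9 of 18 members above 0 and was not called (cameraPR adjusted p = 0.494). Its median was -0.06 while its mean and the test were above 0. The authors' deposited table gave Reg3g, an antibacterial lectin of the epithelium, a log2 fold change of 0.00 ± 0.32.

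In the colon, the sterol list was lower with TURI as well, while the list of immediate early and stress genes was higher. In the authors' deposited table, 67 of 12484 genes passed an adjusted p of 0.05, 32 higher and 35 lower in TURI, with a median change of 1.72-fold. An adjusted p of 3.42e-06, the smallest of the authors' deposited table, was reached by Slc40a1, the iron exporter ferroportin, which was 1.65-fold higher (log2 fold change 0.73 ± 0.12; ENSMUSG00000025993, chromosome 1, 45908068 to 45926523), and by Cebpd, a transcription factor, 1.72-fold higher. The largest rise in the authors' deposited table was that of Nr4a1, an orphan nuclear receptor induced within minutes of many stimuli, at 6.95-fold (log2 fold change 2.80 ± 0.53, adjusted p = 0.000178; ENSMUSG00000023034, chromosome 15, 101254269 to 101274795). Nr4a2 and Areg, the growth factor amphiregulin, were 2.5-fold and 2.5-fold higher in the authors' deposited table. Among the falls in the authors' deposited table were Nnat (-1.57 ± 0.41), Ifit3, an interferon-induced gene (-1.40 ± 0.32), Mfap4, a matrix protein (-1.28 ± 0.31), and Scnn1b, a subunit of the epithelial sodium channel (-0.88 ± 0.20).

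Of 23 measured sterol biosynthesis genes in the colon, 8 fell, 0 rose and 15 did not pass, and 14 fell when adjusted over the list alone (median -0.50, cameraPR adjusted p = 1.5e-20). Fdft1, squalene synthase (ENSMUSG00000021273, chromosome 14, 63145150 to 63179578), Sqle, squalene epoxidase, and Cyp51 had log2 fold changes in the authors' deposited table of -0.81 ± 0.16, -0.67 ± 0.15 and -0.65 ± 0.13. Immediate early and stress genes were above 0 in all 16 measured members: 3 rose (Btg2, Hspa1a and Hspa1b), 10 when adjusted over the list alone, and the median log2 fold change was 0.61 (cameraPR adjusted p = 1.02e-15). The heat shock genes Hspa1a and Hspa1b are near-identical copies, so their split is uncertain; the authors' deposited table gave them 0.78 ± 0.19 and 1.07 ± 0.20. Circadian clock genes had 2 falls (Per3 and Tef) among 19 measured, with 5 lower and 3 higher when adjusted over the list alone (median -0.31, cameraPR adjusted p = 0.0025, and adjusted p = 0.0954 at a correlation of 0.1). In the authors' deposited table Per3 was -0.60 ± 0.16, Tef -0.64 ± 0.15, and Arntl, the transcriptional activator at the core of the clock, 1.06 ± 0.31 with an adjusted p of 0.091.

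**Figure D2:**
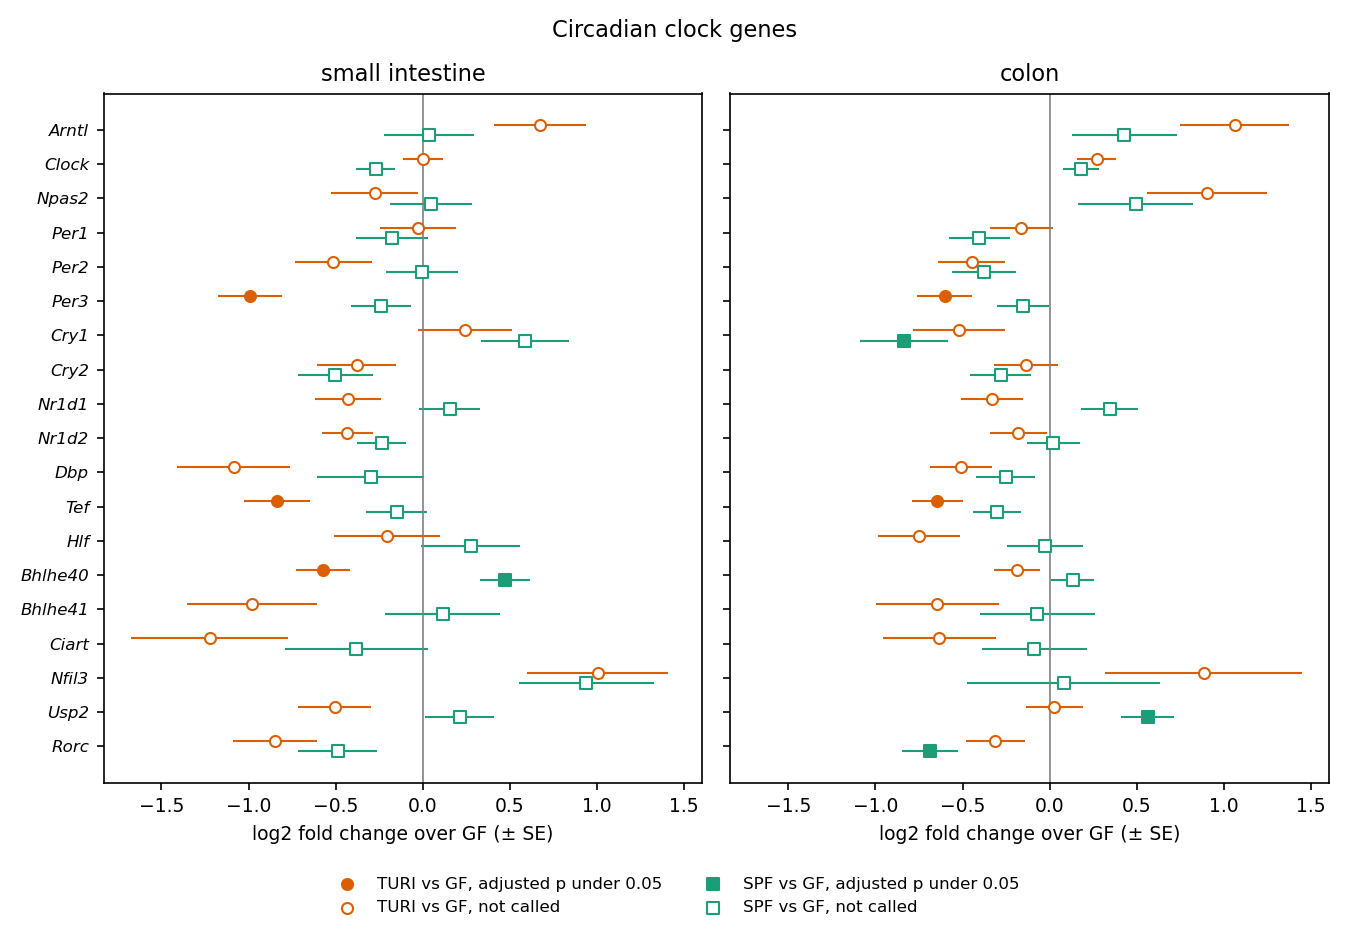
Log2 fold change over GF of each measured circadian clock gene, with its SE as a horizontal bar, from the authors' deposited tables, in the small intestine and the colon. Orange circles are TURI and green squares SPF, filled where the adjusted p was under 0.05; Per3 and Tef were filled below 0 for TURI in both tissues.

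Markers of connective tissue were lower in the TURI colon. Fibroblast markers had 9 of 12 members below 0, of which 1 fell, Col1a1 (-0.77 ± 0.16 in the authors' deposited table), and 4 when adjusted over the list alone (median -0.26, cameraPR adjusted p = 4.54e-05). Adipocyte markers had 0 members past the authors' threshold among 9, and 5 lower when adjusted over the list alone (median -0.78, cameraPR adjusted p = 0.000704). Smooth muscle markers were below 0 in 13 of 14, with 0 lower when adjusted over the list alone (median -0.15, cameraPR adjusted p = 0.00798, and adjusted p = 0.106 at a correlation of 0.1). Erythrocyte markers had 0 of 5 past the authors' threshold and 2 lower when adjusted over the list alone (median -0.30, cameraPR adjusted p = 0.0122, and adjusted p = 0.0713 at a correlation of 0.1). Without its most extreme member that list had an adjusted p of 0.117.

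Cell cycle genes were higher in the TURI colon (24 measured, 19 above 0, median 0.23, 0 past either adjustment, over all genes or adjusted over the list alone, cameraPR adjusted p = 0.000677). So were genes of fatty acid oxidation and PPAR targets (20 measured, median 0.22, 2 higher when adjusted over the list alone, cameraPR adjusted p = 0.000809) and plasma cell markers (11 measured, median 0.80, 0 when adjusted over the list alone, cameraPR adjusted p = 0.00434). Each of these 3 lists had an adjusted p of 0.0713 at a correlation of 0.1. The unfolded protein response list was higher (16 measured, median 0.19, cameraPR adjusted p = 0.00466, and adjusted p = 0.101 at a correlation of 0.1) with 1 rise by either adjustment, also when adjusted over the list alone, of Hsp90b1, an endoplasmic reticulum chaperone, 1.34-fold in the authors' deposited table. Weaker calls were lost at a correlation of 0.05. These were serotonin and enterochromaffin cell genes (13 measured, median 0.14, 0 when adjusted over the list alone, cameraPR adjusted p = 0.0267, then adjusted p = 0.0846) and Paneth cell markers (13 measured, median -0.29, 0 when adjusted over the list alone, adjusted p = 0.0267, then 0.0846). Microbe-induced epithelial defence (18 measured, median 0.08, adjusted p = 0.0325, then 0.12) and fatty acid synthesis (16 measured, median -0.17, adjusted p = 0.0284, then 0.102) were the others. In the defence list 2 genes rose, also when adjusted over the list alone, Ccl28, a chemokine that attracts IgA-secreting cells, and Nox1, an epithelial NADPH oxidase, 1.99-fold and 2.12-fold in the authors' deposited table. In the fatty acid list 1 fell, also when adjusted over the list alone, Scd2, a desaturase, 1.41-fold lower in the authors' deposited table.

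The responses of the small intestine and the colon to TURI were set against each other gene by gene. A total of 57 of 13870 genes differed by the z-test of the difference of the authors' fold changes (Benjamini-Hochberg), 27 with a higher value in the small intestine and 30 in the colon. These differences used shrunken small intestine values; with unshrunken values 58 genes differed. In opposite directions 0 genes were called in the authors' deposited tables. The smallest adjusted p was that of Nr4a1 (in the authors' deposited tables -0.34 in the small intestine, shrunken, or -1.38 unshrunken, and 2.80 in the colon; adjusted p of the difference 0.000352). Fos and Atf3 likewise differed, by -2.28 ± 0.49 (adjusted p = 0.00638) and -2.26 ± 0.53 (adjusted p = 0.0147), and so did the matrix genes Bgn (0.95 ± 0.18, adjusted p = 0.000976) and Col1a1 (1.00 ± 0.22, adjusted p = 0.00638). Among 35 lists, 13 differed between the tissues, first smooth muscle (cameraPR adjusted p = 2.29e-12), higher in the small intestine, and immediate early genes (6.67e-09), higher in the colon. The sterol list was not among them (adjusted p = 0.575).

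Called genes overlapped between the tissues more than independent lists would. For TURI, 8 genes fell in both tissues in the authors' deposited tables against 0.156 expected (one-sided Fisher's exact test, p = 1.96e-12), among them the sterol genes Fdft1, Sqle, Lss and Hmgcs1, the desaturase Scd2, and the clock genes Tef and Per3. Only Hspa1a rose in both by the authors' deposited tables, against 0.0679 expected (one-sided Fisher's exact test, p = 0.0658). Both tissues may come from the same mice, which the labels do not state, and shared variation between them would add to this overlap.

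The comparison of SPF with GF asked what a complex microbiota changes. In the small intestine 628 genes were higher and 337 lower in SPF among 14337 with an adjusted p in the authors' deposited table, and 317 of the 965 had changed at least 2-fold. The antibacterial lectins Reg3b and Reg3g rose, as did antibody genes and MHC class II genes, while genes of drug metabolism went both ways. Mptx2, a pentraxin of Paneth cells (ENSMUSG00000079180, chromosome 1, 173274382 to 173277777, protein coding), was 35.8-fold higher in the authors' deposited table, with a log2 fold change of 5.16 ± 0.27 and an adjusted p of 7.28e-77. Ces2a, a carboxylesterase (ENSMUSG00000055730, chromosome 8, 104734003 to 104741634), was 10.2-fold higher in the authors' deposited table (3.36 ± 0.19, adjusted p = 1.25e-62), although near-identical Ces2 copies make its reads uncertain. Reg3b (ENSMUSG00000071356, chromosome 6, 78370657 to 78373466) and Reg3g, antibacterial lectins, were 5.05-fold and 8.21-fold higher in the authors' deposited table, with adjusted p of 4.3e-38 and 6.74e-21.

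Among the falls in the small intestine of SPF mice, Angptl4, an inhibitor of lipoprotein lipase known to be held down by a microbiota (ENSMUSG00000002289, chromosome 17, 33773750 to 33781830), had a log2 fold change of -2.48 ± 0.21 and an adjusted p of 1.84e-29 in the authors' deposited table. Rdh7, a retinol dehydrogenase, Atg16l2, an autophagy gene, and Slc5a4b, a sugar transporter family member, were 3.28-fold, 3.03-fold and 3.41-fold lower in the authors' deposited table. The metallothionein Mt2 and Tnfsf15, a cytokine of the tumour necrosis factor family, were 3.64-fold and 3.66-fold lower there, by the authors' deposited table.

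The microbe-induced defence list had 12 rises, 0 falls and 6 genes that did not pass among 18 measured, and 13 rises when adjusted over the list alone (median log2 fold change 1.64, cameraPR adjusted p = 1.17e-31). Nos2, the inducible nitric oxide synthase, and Duoxa2, the maturation factor of the oxidase DUOX2, were 17.8-fold and 14-fold higher in the authors' deposited table, and Fut2, a fucosyltransferase, 11.3-fold higher. Paneth cell markers had 11 rises among 14, 13 when adjusted over the list alone (median 0.61, cameraPR adjusted p = 5.54e-29), with Mmp7 1.98-fold and Ang4 2.24-fold higher in the authors' deposited table; the defensin genes of the list are near-identical copies. Plasma cell markers had 8 rises among 11, also 8 when adjusted over the list alone (median 2.80, cameraPR adjusted p = 6.71e-25), led in the authors' deposited table by Igha, the constant chain of IgA (3.26 ± 0.31; ENSMUSG00000095079, chromosome 12, 113254830 to 113260236), Igkc (2.96 ± 0.34) and Jchain (2.80 ± 0.31).

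MHC class II genes had 6 rises among 9 in the SPF small intestine, 7 when adjusted over the list alone (median 1.26, cameraPR adjusted p = 1.4e-28), among them Cd74, the invariant chain, 3.52-fold higher in the authors' deposited table. Interferon-stimulated genes had 12 rises and 0 falls among 31, 17 when adjusted over the list alone (median 0.91, cameraPR adjusted p = 7e-17); Cxcl9, a T cell chemokine, and Psmb8, an immunoproteasome subunit, were 6.52-fold and 2.25-fold higher in the authors' deposited table. Macrophage and dendritic cell markers had 10 rises among 15, 13 when adjusted over the list alone (median 0.82, cameraPR adjusted p = 4.96e-18). T and intraepithelial lymphocyte markers had 6 rises among 9, 8 when adjusted over the list alone (median 1.81, cameraPR adjusted p = 2.64e-09), with Cd4 5.47-fold and Ccl5 4.24-fold higher in the authors' deposited table. Tuft cell markers had 5 rises among 11, with 5 higher and 1 lower when adjusted over the list alone (median 0.63, cameraPR adjusted p = 3.88e-05).

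Metabolic lists went both ways in the SPF small intestine. Xenobiotic metabolism had 8 rises and 3 falls among 26, 8 and 4 when adjusted over the list alone. With a median of 0.08, its cameraPR adjusted p of 9.42e-05 was lost on ranks of the statistic, where the adjusted p was 0.354. In the authors' deposited table Cyp3a11 and Cyp2c55, cytochrome P450 enzymes, were 9.6-fold and 8.16-fold higher. Steroid and retinoid metabolism had 5 falls among 19, 8 when adjusted over the list alone (median -0.07, cameraPR adjusted p = 6.58e-05; adjusted p = 0.0963 on ranks), with Hsd11b2, which inactivates glucocorticoids, 2-fold lower in the authors' deposited table. Sterol biosynthesis had 4 falls among 24, 6 when adjusted over the list alone (median -0.20, cameraPR adjusted p = 2.5e-05), with Hmgcs1 at -0.40 ± 0.10 in the authors' deposited table. Calls for cell cycle (median -0.22, adjusted p = 0.00769), fibroblast (0.16, 0.0256), cholesterol efflux (0.22, 0.0256), fatty acid synthesis (-0.21, 0.0376) and mitochondrial genes (-0.15, 0.0376) were lost at a correlation of 0.05, with adjusted p of 0.0668, 0.072, 0.07, 0.117 and 0.0776. Adjusted over the list alone, these 5 lists had 2, 3, 4, 4 and 3 changed members.

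**Figure D3:**
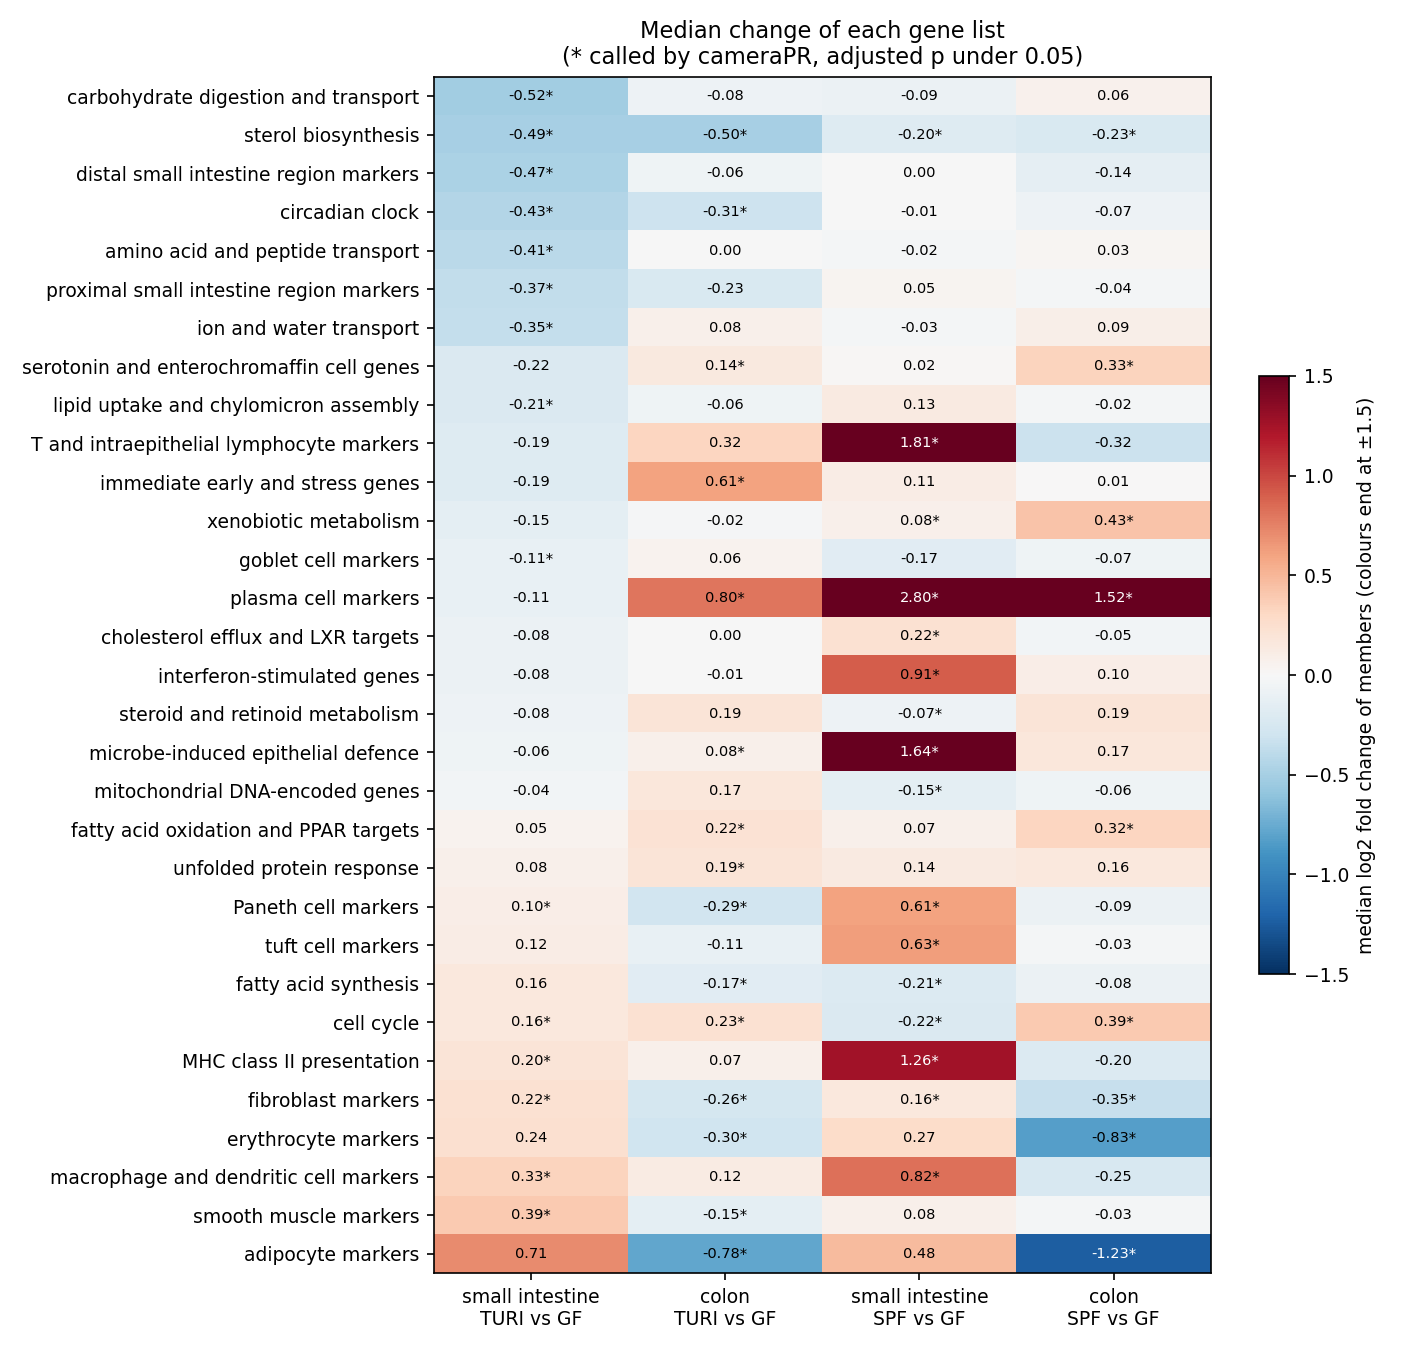
Median log2 fold change over GF of the measured members of each gene list called in at least 1 of the 4 comparisons (red above 0, blue below 0, colours ending at ±1.5), with the value printed in each cell and an asterisk where the cameraPR adjusted p was under 0.05. Sterol biosynthesis was below 0 with an asterisk in all 4 comparisons, at -0.49 and -0.50 for TURI and -0.20 and -0.23 for SPF.

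In the colon of SPF mice, the lists of xenobiotic metabolism and of fatty acid oxidation and PPAR targets were higher. Fatty acid synthesis was not called (median -0.08, cameraPR adjusted p = 0.345). Sodium channel subunits and fibroblast markers were among the falls. The authors' deposited table held 223 higher and 242 lower genes among 14489 with an adjusted p. Cyp2c55 (ENSMUSG00000025002, chromosome 19, 39007019 to 39042693) was 18.9-fold higher in the authors' deposited table, with a log2 fold change of 4.24 ± 0.30 and an adjusted p of 2.08e-40. Ces2a, Cbr3, a carbonyl reductase, and Abcb1a, the drug efflux pump P-glycoprotein (ENSMUSG00000040584, chromosome 5, 8660077 to 8748575), were 3.02-fold, 2.87-fold and 2.59-fold higher in the authors' deposited table. The xenobiotic list had 7 rises and 1 fall among 22, 10 and 1 when adjusted over the list alone (median 0.43, cameraPR adjusted p = 3.14e-18). Cyp4f14 was 2.67-fold lower in the authors' deposited table (adjusted p = 2.46e-21), and the sodium channel subunits Scnn1b (ENSMUSG00000030873, chromosome 7, 121865038 to 121918514) and Scnn1g were 2.66-fold and 3.42-fold lower. The water channel Aqp8 was 1.69-fold higher in the authors' deposited table.

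Fatty acid oxidation and PPAR targets had 6 rises among 20 in the SPF colon, 9 when adjusted over the list alone (median 0.32, cameraPR adjusted p = 2.94e-10), with Cpt1a, which admits fatty acids to mitochondria, 1.73-fold higher in the authors' deposited table. Cell cycle genes were above 0 in all 24 members, of which 4 rose and 12 when adjusted over the list alone (median 0.39, cameraPR adjusted p = 2.59e-10); Hells was 1.94-fold higher in the authors' deposited table. Fibroblast markers were below 0 in all 12, with 5 falls and 6 when adjusted over the list alone (median -0.35, cameraPR adjusted p = 1.21e-06), among them Col1a1 (-0.53 ± 0.15) and Dpt (-0.47 ± 0.11) in the authors' deposited table. Sterol biosynthesis had 3 falls among 23, 5 when adjusted over the list alone (median -0.23, cameraPR adjusted p = 1e-05), with Insig1, a sterol sensor, 1.98-fold lower in the authors' deposited table.

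Plasma cell markers had 1 rise among 11 in the SPF colon and 7 when adjusted over the list alone (median 1.52, cameraPR adjusted p = 0.000443), and the authors' deposited table gave Igha 2.41 ± 0.83 with an adjusted p of 0.0842. Erythrocyte markers had 2 falls among 5, also 2 when adjusted over the list alone (median -0.83, cameraPR adjusted p = 0.00495), but without its most extreme member the list was not called (adjusted p = 0.0547). Hba-a1, an alpha-globin (ENSMUSG00000069919, chromosome 11, 32283511 to 32284465), was 8.73-fold lower with a wide SE of 0.92 in the authors' deposited table. Adipocyte markers had 1 fall among 9, 3 lower and 1 higher when adjusted over the list alone (median -1.23, cameraPR adjusted p = 0.0144, adjusted p = 0.102 at a correlation of 0.1 and adjusted p = 0.0716 without its most extreme member). The serotonin list had 1 rise among 13, also 1 when adjusted over the list alone (median 0.33, cameraPR adjusted p = 0.0435, and adjusted p = 0.133 at a correlation of 0.05). That gene was Tph1, the enzyme that starts serotonin synthesis in enterochromaffin cells (ENSMUSG00000040046, chromosome 7, 46644641 to 46672537), 2.09-fold higher in the authors' deposited table with an adjusted p of 0.0294. Its counterparts in the authors' deposited tables were 1.64-fold (adjusted p = 0.0388) in the SPF small intestine, 0.55 ± 0.34 on the log2 scale (adjusted p = 0.577) in the TURI colon and -0.50 ± 0.26 (adjusted p = 0.505) in the TURI small intestine. Slc6a4, the serotonin transporter, was called in 0 comparisons, with log2 fold changes in the authors' deposited tables of -0.29 ± 0.17 and 0.06 ± 0.17 for TURI and -0.39 ± 0.16 and 0.37 ± 0.16 for SPF, small intestine first.

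SPF effects differed between the tissues in 499 of 13870 genes by the z-test of the difference (Benjamini-Hochberg), 329 with the higher value in the small intestine and 170 in the colon. Mptx2 differed by 4.91 ± 0.44 and Duoxa2 by 3.14 ± 0.45, both higher in the small intestine, and Ces1f by -2.69 ± 0.34, higher in the colon. By the authors' adjusted p, 23 genes were called in opposite directions in the tissues in the authors' deposited tables, among them Saa1, an acute phase protein (3.14 in the small intestine and -0.55 in the colon), and Mal (3.45 and -1.79). No count expected from independent lists was worked out for opposite directions, so 23 is not shown to exceed it. Called in the same direction in both were 49 higher genes against 9.56 expected from independent lists (one-sided Fisher's exact test, p = 7.9e-22) and 26 lower genes against 5.54 (5.44e-11). Of 35 lists, 15 differed between the tissues, 11 higher in the small intestine, with microbe-induced defence first (adjusted p = 4.15e-18) and MHC class II next (4.79e-16).

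SPF was also set against TURI within each tissue, through the difference of their fold changes over GF. With shrunken TURI values, 286 of 14623 genes differed in the small intestine (z-test, Benjamini-Hochberg), 246 higher in SPF and 40 higher in TURI, with Mptx2 (4.66 ± 0.34), Ces2a (3.39 ± 0.26) and Reg3b (2.42 ± 0.23) first, and Angptl4 at -2.54 ± 0.27. With unshrunken fold changes 206 genes differed. In the colon 54 of 14776 genes differed, 33 higher in SPF and 21 higher in TURI, with Cyp2c55 (4.18 ± 0.44), Cbr3 (1.70 ± 0.21) and Ces2a (1.43 ± 0.18) first. By list, SPF exceeded TURI in the small intestine for defence (cameraPR adjusted p = 1.19e-35) and plasma cell genes (2.62e-33). In the colon it did so for xenobiotic metabolism (adjusted p = 1.94e-15), while immediate early genes were higher in the TURI colon (adjusted p = 1.33e-09). These errors ignore the shared GF libraries, which makes them too large in the colon, while in the small intestine shrunken errors make them too small for some genes. With the standard error of TURI against GF, which equal variances would give, 971 and 357 genes differed.

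Genes called for both TURI and SPF in the same direction in the authors' deposited tables numbered 16 in the small intestine, 6 higher (1.49 expected from independent lists) and 10 lower (1.51), among them Ahrr, Il1r1, Hmgcs1, Lss and Scd2. In the opposite direction 3 genes were called, Fam84a, Bhlhe40 and Cldn4, each lower in TURI and higher in SPF by the authors' deposited tables. The count expected from independent lists was not worked out for opposite directions, so 3 is not shown to exceed it. In the colon 10 higher (0.564 expected) and 10 lower genes (0.648 expected) were shared and 0 were opposite, among them Slc40a1, Col1a1, Sparc and Scnn1b. Simulated unchanged groups sharing the GF libraries gave a mean of 0.385 shared calls in the small intestine and 0.255 in the colon, at most 3 and 2. No gene was changed in these simulations, so their counts set no expectation for called lists of the real length. Genes were simulated independently, so shared calls among genes that vary together could reach higher. Part of the excess may come from the shared GF libraries, which could not be split without values per library.

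Across genes, which are not independent replicates, the fold changes of TURI and SPF correlated with a Pearson r of 0.314 and Spearman rho of 0.348 over 11610 genes in the small intestine with shrunken TURI values, with r of 0.301 unshrunken, and with r of 0.534 and rho of 0.442 over 12109 genes in the colon. Simulated unchanged groups with shared GF libraries gave r of 0.471 in each tissue. With unshrunken values, the scale of the simulation, the covariance in the small intestine was 0.0296 against a simulated mean of 0.0229 and maximum of 0.0258. In the colon it was 0.0523 against 0.0249 and a maximum of 0.0276. The simulation drew genes independently, so these maxima are no bound for genes that vary together. Without genes of an SE above 0.8, a limit chosen after the data were seen, the colon had r of 0.448 and a covariance of 0.0368 against 0.0234 simulated.

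Genes fixed for reporting whatever their result included Fabp6, the ileal bile acid binding protein, and Cd36, a fatty acid translocase, neither of which was called in any comparison. In the authors' deposited tables Fabp6 in the small intestine had log2 fold changes of -0.18 ± 0.29 for TURI and -0.22 ± 0.27 for SPF, and Cd36 of 1.07 ± 0.66 and 1.38 ± 0.62. Angptl4 with TURI was at 0.10 ± 0.21 in the small intestine and 0.54 ± 0.38 in the colon, and Saa1 at -0.80 ± 0.72 and 0.03 ± 0.16, with 0 calls in the authors' deposited tables.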

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

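The test of each gene for a tissue difference was set before the data were examined, while the list tests on that difference and the tests of explanations were chosen after the result was seen. Between the tissues, 57 genes responded differently to TURI and 499 to SPF (z-test, Benjamini-Hochberg). With TURI, smooth muscle markers (cameraPR adjusted p of the difference 2.29e-12), fibroblast markers (1.51e-07) and Paneth cell markers (0.00289) were higher in the small intestine and lower in the colon. The Paneth difference had an adjusted p of 0.0634 at an inter-gene correlation of 0.1. With SPF, cell cycle genes were lower in the small intestine and higher in the colon (adjusted p = 1.23e-12), and fibroblast markers the reverse (adjusted p = 1.56e-07). The small intestine calls behind this were lost at a correlation of 0.05, with adjusted p of 0.0668 for cell cycle and 0.072 for fibroblast markers. For TURI the Paneth calls of both tissues were lost there too, with adjusted p of 0.076 and 0.0846. The fibroblast results of TURI and SPF rest on the same GF libraries of each tissue, so they are not independent. A difference particular to those GF libraries would enter both and was not separated.

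For the lower absorptive genes and higher muscle genes in the small intestine with TURI, a larger share of muscle in the pieces would lower every epithelial list alike. The absorptive lists, with 47 genes, were lower than the goblet and Paneth lists, with 27 genes, by a mean log2 fold change of -0.263 (95% interval -0.392 to -0.124). That interval measures spread among genes, not among mice. Goblet markers had a mean of -0.14 and Paneth markers of 0.15, so only the Paneth list moved against the absorptive lists. The difference leans against muscle share as the whole cause of the absorptive fall without settling it. Muscle share stays open as a cause of the muscle and fibroblast rise. A sampling site shifted along the intestine would move proximal and distal markers apart, but without the shared member their medians were -0.31 and -0.46, although 5 region markers were also in the absorptive lists. More crypt relative to villus could bear on the absorptive fall, as cell cycle genes were higher (cameraPR adjusted p = 0.00177, adjusted p = 0.0242 at a correlation of 0.05 and 0.0941 at 0.1), but stem cell markers were not called (median 0.08, adjusted p = 0.658). Whether that explanation would also raise muscle genes was not tested. It and a response to colonisation itself both stay open.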

How the results depend on the processing

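No paired analysis was possible because only the authors' comparison tables were used, without values per library. For the same reason a replicate block, leaving out replicates, edgeR or DESeq2 on counts and other splits of the libraries could not be run or counted, and an overlap by the ANOVA p was not defined, as that p is shared by both pairs of a tissue. Of 72 alternatives for counts and correlations, 50 were labelled the same and 22 moved. Counts were judged by a fixed ratio to the main count and correlations by the simulated spread, so a reversal could not show. Of 434 for lists, 367 were the same, 60 weaker and 7 stronger, and of 746 for named genes 677, 14 and 55. In both 0 were reversed, although a reversal was possible only where an alternative gave its own direction.

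At adjusted p under 0.1 the calls were 198 (TURI, small intestine), 124 (TURI, colon) and 753 (SPF, colon), and under 0.01 they were 22, 32, 530 (SPF, small intestine) and 230. With an absolute log2 fold change of at least 1 they were 4, 13, 317 and 94, the first with shrunken values and 16 with unshrunken values. Those shifts follow from the thresholds. The ANOVA tables gave 1299 and 629 because they test any difference among 3 groups. For SPF against TURI, the standard error of TURI against GF gave 971 and 357 genes. Shared TURI and SPF calls at 0.1 were 52 and 42. Over all genes r was 0.344 in the small intestine, with shrunken TURI values, and 0.475 in the colon, and without genes of an SE above 0.8 it was 0.448 in the colon. At an inter-gene correlation of 0.1, 9 and 4 lists were called for TURI. For these last settings the cause was not tested.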

Other observations

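A few hormone genes rose in the SPF small intestine. In the authors' deposited table, the enteroendocrine peptide genes Cck, Pyy, Nts and Sst had log2 fold changes of 0.83, 0.51, 0.51 and 0.50, each called, although their list as a whole was not (cameraPR adjusted p = 0.084). Gsdmc3, a member of the pore-forming gasdermin family, was called higher in the small intestine (1.62) and lower in the colon (-0.38) by the authors' deposited tables. Il18, an epithelial cytokine, had a log2 fold change of 0.94 ± 0.12 in the colon of SPF mice (adjusted p = 5.7e-12 in the authors' deposited table).

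The tests below were all chosen after the result was seen, among them the clock sets, the rule for the colon cluster and the added alternatives. For lower sterol genes with TURI, GF libraries that happened to be high would lower TURI and SPF alike, yet SPF exceeded TURI in 18 of 24 members in the small intestine and 17 of 23 in the colon. The cameraPR adjusted p of that difference was 0.000269 (0.00756 at a correlation of 0.05) and 0.00172 (0.0405), with unshrunken values, against this as the whole cause; with shrunken values in the small intestine it was 0.0082 (0.0567), and at 0.1 it was 0.142 there and 0.194 in the colon. A lower share of epithelium in the colon would raise connective tissue, but fibroblast markers had a median of -0.26 and smooth muscle of -0.15; in the small intestine those medians were 0.22 and 0.39, so a lower share of epithelium stays open there. Another clock phase at collection may contribute. For TURI, the mean of Arntl, Npas2, Clock, Cry1 and Nfil3 exceeded that of Per2, Per3, Nr1d1, Nr1d2, Dbp, Tef, Hlf, Ciart and Bhlhe41. The difference was 1.07 ± 0.155 in the small intestine and 1.05 ± 0.174 in the colon. For SPF it was 0.35 ± 0.146 and 0.17 ± 0.168. In the small intestine, 3 of the first 5 genes were above 0 for TURI and 4 for SPF. Of the other 9, 9 were below 0 for TURI and 6 for SPF. These errors treat the genes as independent, which they are not, so they may be too small. A smaller shift in the SPF small intestine therefore stays uncertain. Collection times were not in the labels, and a lowering of sterol and clock genes by colonisation stays a hypothesis that the same values could fit.

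In the colon 18 genes, chosen by a baseMean of at least 20, an SE above 0.8 and both log2 fold changes under -1.5, had medians of -3.05 for SPF and -3.17 for TURI, low by the selection itself. By the authors' adjusted p, 8 of the 18 were called for SPF and 0 for TURI. Blood in the GF pieces would raise both globin chains, but Hba-a1, picked for its large fall, differed from Hbb-bs by -2.85 ± 0.942, against blood as the whole cause of that fall. All 5 erythrocyte markers were below 0 for SPF (median -0.83, 2 called), so a smaller difference in blood stays open. Reads shared between near-identical copies could link these genes, as 16 of the 18 were annotated as pseudogenes or miscellaneous RNA, against 0 of the 9 other genes past the same limits of baseMean and SE (one-sided Fisher's exact test, p = 1.17e-05). No per-library value tells which GF libraries carry them. Whether reads were shared between these genes was not examined, and Hba-a1 and Hba-x were annotated as protein coding. In the small intestine, 16 of the 18 were measured, with a median of -0.82 for SPF and a median SE of 1.27. A technical cause of the Hba-a1 fall in the colon was thus not tested. That cause and a response to colonisation both stay open.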
